A study of Homo sapiens with 9 samples.

How the data were processed

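RNA of 9 samples of H9 cells was measured on one-colour arrays, 3 samples for each of the SSEA5-positive, APA-negative and APA-positive populations. Per the labels, undifferentiated cells grew on irradiated mouse feeder cells with basic fibroblast growth factor, and treated cells grew on Matrigel without it and with BMP4 at 50 ng/ml for 2.5 days, so culture and treatment change together. Cells were released with Versene and sorted with antibodies to APA and SSEA5, per the labels. The series describes 3 independent differentiation experiments. Per the labels' protocols, 50 ng of column-purified total RNA was amplified with a whole transcriptome amplification kit and labelled with biotin.

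The authors deposited log2 values of 53617 probe sets per array that were already normalized between arrays. Their method of summarization and normalization is not given in the sources used here. The sorted values of the 9 arrays were close but not identical, with a largest spread of 0.246, so the last step was not a full quantile normalization of these probe sets. Array medians lay between 5.01 and 5.09. No array duplicated another. The deposited values were used without further normalization.

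The platform's probe annotation paired 1 gene symbol with 16098 probe sets and more than 1 with 0, and the other 37519 were not named here. All 16098 symbols matched RefSeq (GRCh38.p14) by gene identifier, unchanged. For each of 14884 genes, the probe set with the highest mean over all arrays was used. Of these genes, 779 had more than 1 probe set, and in no comparison did probe sets of 1 gene pass in opposite directions. The array's genome build was not stated, so no positions are given. Genes such as TFAP2A, TBXT, ID1, TDGF1, HLA-G and CDH1 had no named probe set and were not analysed here.

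A linear model with a mean per population was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 6 residual and 3.53 prior degrees of freedom), with the package data.table (version 1.17.8). The 3 comparisons were APA-positive against SSEA5-positive, APA-negative against SSEA5-positive and APA-positive against APA-negative cells, with a moderated F test over the 3 populations. P values were adjusted by Benjamini and Hochberg over all genes, with a threshold of 0.05. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. An exact permutation of 3 against 3 arrays cannot give a p under 0.1, so p values across genes rest on limma's pooled spread.

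The comparisons, the tests, 37 gene lists (671 genes, 412 measured), the genes to be named and most alternative settings were chosen before the data were examined. Lists with at least 5 measured genes, 32 in number, were tested with limma's camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the lists of a comparison. Camera compares a list with the other genes, and fry tests whether a list's genes move on balance one way. Left out were H type 1 glycan synthesis (1 gene measured), basement membrane (4), integrins (0), mitochondrially encoded transcripts (0) and replication-dependent histones (0). Named genes are those with the 8 largest rises and 8 largest falls per comparison among called genes whose groups do not overlap, without symbols of uncharacterised or small RNA genes. Further named genes are ENPEP, POU5F1, NANOG, SOX2, GATA2, GATA3, TFAP2A, TFAP2C, CDX2, TBXT, KRT7, HAND1 and DNMT3B, up to 4 called members with the largest change per described list, and the 6 genes with the largest smaller step per direction of the graded and outside-range patterns. Genes outside this rule are said to have been chosen after their values were seen.

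Whether replicate numbers pair the arrays was checked from the correlation across genes of deviations from population means. APA-negative and APA-positive arrays with the same number correlated at 0.224, 0.349 and 0.335, and those with different numbers at -0.261 to -0.0643, so the numbers were taken to pair these populations. The pairing comes from these correlations, since the labels do not state it. SSEA5-positive arrays did not all pair by number. Replicate 3 correlated best with arrays numbered 3 (0.173 with APA-negative, 0.272 with APA-positive) and replicate 2 with arrays numbered 2 (0.0784 and 0.132). Replicate 1 also correlated best with arrays numbered 2 (0.221 and 0.176).

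Alternatives were quantile normalization on top, centring of each array, a filter on dim probe sets, the mean of a gene's probe sets, eBayes with trend and robust, a fit of only the 2 groups compared, the replicate number as a block, each array left out in turn, treat at a log2 of 0.5, a threshold of 0.01, every probe set tested, an estimated correlation and fry. Chosen after seeing the data were fits without APA-negative replicate 3 and SSEA5-positive replicate 3, fits without all arrays numbered 3, and the block in a fit of APA-positive and APA-negative arrays alone. The code was tested on simulated data of 14884 genes. For APA-positive against SSEA5-positive, 73% of genes changed by a log2 of 1 and 97% of those changed by 2 were recovered, with 8 false calls among 178. For APA-positive against APA-negative these were 74%, 98% and 8 among 180, and APA-negative against SSEA5-positive, with 0 changed genes, gave 0 calls. A shifted list among 31 was called by camera (adjusted p = 6.27e-54) with 0 of the unshifted lists. The simulated genes were drawn independently, so false calls among correlated genes were not tested. In the data the estimated correlation of the G2/M list, for example, was 0.884.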

Results

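The data were 9 one-colour arrays of human embryonic stem cell line H9, in 3 sorted populations with 3 arrays each. SSEA5-positive cells were undifferentiated cells, sorted for SSEA5, a cell surface glycan of pluripotent cells. APA-positive and APA-negative cells came from H9 cultures treated with bone morphogenetic protein 4 (BMP4, 50 ng/ml) for 2.5 days and sorted on aminopeptidase A (APA), a cell surface enzyme encoded by ENPEP. Per the labels, undifferentiated cells grew on feeder cells with basic fibroblast growth factor, and treated cells on Matrigel without it. In comparisons with SSEA5-positive cells, culture, growth factor and BMP4 treatment thus change together. Array medians lay between 5.01 and 5.09 on the log2 scale over 53617 probe sets. Across probe sets, which are not independent replicates, pairs of arrays of 1 population correlated at 0.972 to 0.985 and APA-positive with SSEA5-positive arrays at 0.942 to 0.963. The number of arrays limits the precision, and the median standard error of a log2 difference was 0.135. Differences below are log2 differences ± SE between group means of 3 arrays, with adjusted p from limma over 14884 genes.

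ENPEP itself served as a check of the sort and not as a finding. Its log2 value (probe set 16969766) averaged 5.04 ± 0.20 in SSEA5-positive, 7.40 ± 0.37 in APA-negative and 10.06 ± 0.25 in APA-positive cells (SD, n = 3 each). It was 6.32-fold higher in APA-positive than in APA-negative cells (2.66 ± 0.20, adjusted p = 2.81e-04). APA-negative cells still held 5.14-fold more ENPEP signal than SSEA5-positive cells (2.36 ± 0.20, adjusted p = 1.82e-04).

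**Figure D1:**
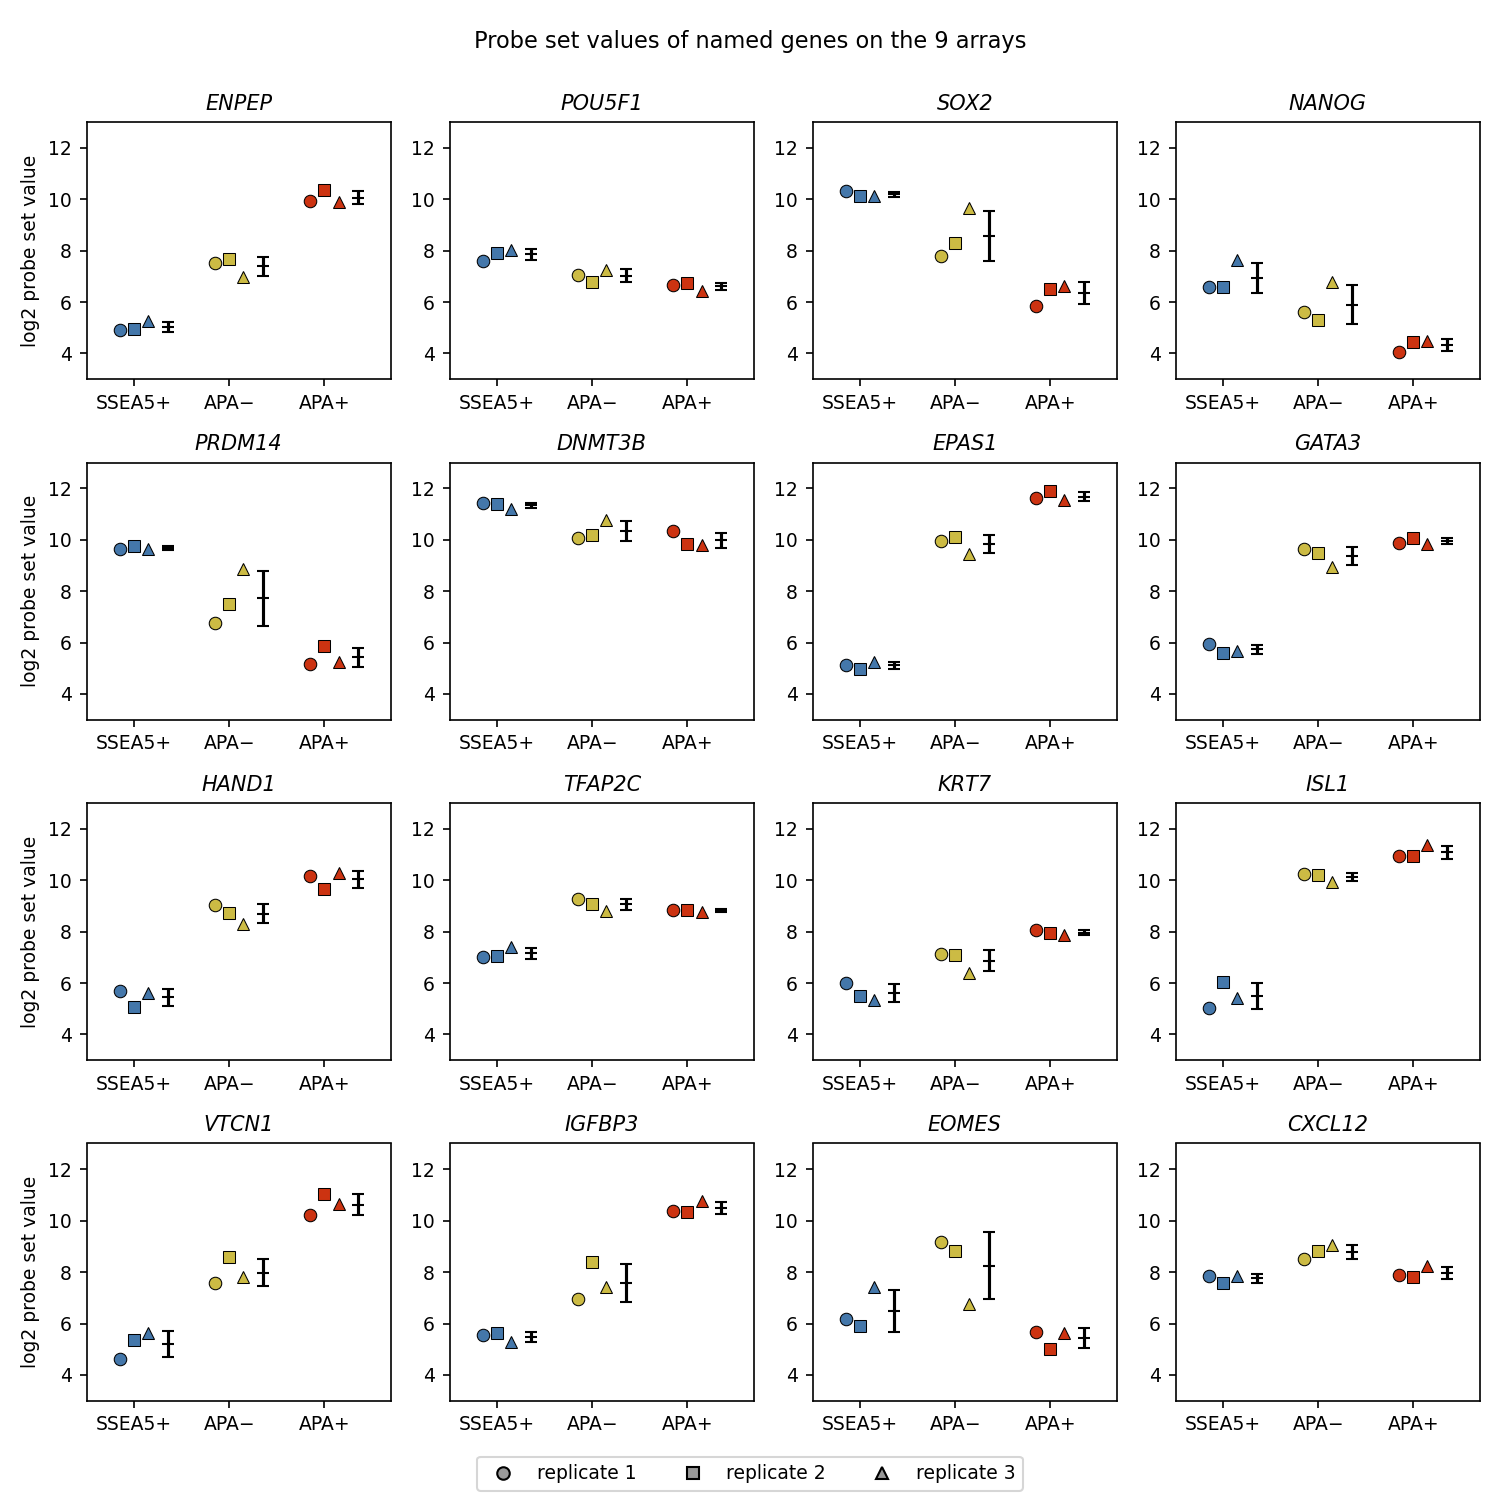
Log2 probe set values (y axis) of 16 genes on each of the 9 arrays, grouped by sorted population along the x axis, with points for arrays and bars for the mean ± SD of 3 arrays. ENPEP rose from a mean of 5.04 in SSEA5-positive cells to 10.06 in APA-positive cells, and SOX2 fell from 10.19 to 6.34.

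The comparison of APA-positive with SSEA5-positive cells asked how BMP4-treated cells that carried APA differed from undifferentiated cells. By camera the trophectoderm, amnion, keratin and junction lists shifted up, and the pluripotency and DNA replication lists down, of which only trophectoderm and amnion also passed with an estimated correlation. The largest rise was in EPAS1 (probe set 16879721), a hypoxia-inducible transcription factor, which was 94.9-fold higher (6.57 ± 0.17, adjusted p = 6.03e-08). It averaged 11.67 ± 0.18 against 5.11 ± 0.14 (SD, n = 3 each). WLS (probe set 16688339), which carries Wnt proteins to the cell surface, was 50.6-fold higher (5.66 ± 0.29, adjusted p = 2.61e-06). The largest fall was in JAKMIP2-AS1 (-5.67 ± 0.38, adjusted p = 1.26e-05), an antisense transcript. Of 14884 genes, 2995 changed, 1543 higher and 1452 lower in APA-positive cells, and 996 of them differed by a log2 of at least 1 (590 higher, 406 lower). Groups of 3 arrays did not overlap for 33.4% of genes, where chance gives 10%, and every gene given with a fold in this comparison was among them. Of 32 lists tested, 11 passed camera, and 2 with an estimated correlation.

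Pluripotency genes fell together in APA-positive cells. Of 26 measured, 22 fell and 0 rose (23 fell and 1 rose adjusted over the list alone), with a median of -2.13 and camera adjusted p = 3.65e-17, and adjusted p = 0.10 with an estimated correlation. PRDM14, a transcriptional regulator that maintains pluripotency (probe set 17078048), fell by 4.26 ± 0.43, and SOX2, a core pluripotency factor (probe set 16948461), fell by 3.85 ± 0.41 (adjusted p = 1.17e-04 and 1.54e-04). The other core factors NANOG (-2.60 ± 0.38, adjusted p = 0.00109) and POU5F1 (-1.24 ± 0.15, adjusted p = 3.86e-04) and the de novo DNA methyltransferase DNMT3B (-1.36 ± 0.20, adjusted p = 0.00126) fell less. The largest falls among pluripotency genes also included SFRP2 (-4.83 ± 0.44), a secreted Wnt modulator, and USP44 (-4.11 ± 0.36), a deubiquitinase. The number of rises was 1 without APA-negative replicate 1 or 3. DPPA2, L1TD1, LIN28B and ZFP42 did not pass the test and were named after their values were seen.

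Trophectoderm regulators, transcription factors of the outer layer of the blastocyst and its descendants, rose in 19 of 23 measured cases and fell in 0 (19 rose adjusted over the list alone, camera adjusted p = 8.79e-17, and adjusted p = 0.0446 with an estimated correlation). Besides EPAS1, the rises included TBX3 (5.25 ± 0.17, adjusted p = 1.90e-07), HAND1 (4.57 ± 0.24, adjusted p = 2.83e-06), DLX5 (4.53 ± 0.27, adjusted p = 7.13e-06) and GATA3 (4.19 ± 0.17, adjusted p = 1.02e-06). Smaller rises were those of TFAP2C (1.65 ± 0.14, adjusted p = 4.57e-05), GATA2 (1.13 ± 0.26, adjusted p = 0.0128) and CDX2 (0.44 ± 0.09, adjusted p = 0.00857). Of 9 amnion genes, 7 rose (8 adjusted over the list alone, camera adjusted p = 5.96e-09, and adjusted p = 0.0446 with an estimated correlation), and TBX3 and TFAP2B belong to both lists. They included ISL1 (5.59 ± 0.24, adjusted p = 1.04e-06), a LIM homeodomain factor, VTCN1 (5.41 ± 0.33, adjusted p = 7.13e-06), an immune checkpoint ligand, and IGFBP3, a binding protein of insulin-like growth factors, at 10.49 ± 0.24 against 5.49 ± 0.19 (SD, n = 3 each). Of 32 placental hormone and syncytiotrophoblast genes, 15 were measured. CGA, CGB3, CGB5, CGB7, CGB8, ERVW-1, ERVFRD-1, HSD3B1, CYP19A1 and CYP11A1 were among those without a named probe set. Of the 15 measured, 3 rose and 3 fell (the same counts adjusted over the list alone), with camera adjusted p = 0.804. The number of rises was 1 without APA-negative replicate 1 or APA-positive replicate 1 or 2 or SSEA5-positive replicate 1 or 3, and that of falls 1 without APA-negative replicate 2 or APA-positive replicate 2 or 3 or SSEA5-positive replicate 2 or 3. The protease PAPPA2 (1.74 ± 0.28) showed the largest rise among them. Of 15 extravillous trophoblast genes, 7 were measured, and HLA-G, MMP2, MMP9, ITGA1 and ITGA5 were not. Of the 7, the vascular endothelial growth factor receptor FLT1 (-3.03 ± 0.23) fell and no other passed the test in either adjustment (camera adjusted p = 0.438).

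All 6 measured simple epithelial keratins rose, also adjusted over the list alone (camera adjusted p = 2.04e-07, and adjusted p = 0.0519 with an estimated correlation), among them KRT19 (3.05 ± 0.16, adjusted p = 2.80e-06), KRT7 (2.35 ± 0.22, adjusted p = 6.84e-05) and KRT18 (2.31 ± 0.13, adjusted p = 4.43e-06). Epithelial junction genes rose in 10 of 17 cases and fell in 1, OCLN, a gene named after its values were seen (the same counts adjusted over the list alone, camera adjusted p = 1.33e-05, and adjusted p = 0.0519 with an estimated correlation). Its fall did not pass without APA-positive replicate 2 or 3 or without SSEA5-positive replicate 2 or 3. The epithelial transcription factor GRHL1 (3.72 ± 0.35, adjusted p = 7.59e-05) and the desmosomal proteins DSP (2.60 ± 0.20, adjusted p = 2.59e-05) and PKP2 (2.36 ± 0.18, adjusted p = 2.42e-05) rose. Members of the mesenchymal transition list moved both ways, with 4 of 10 higher and 1 lower (5 and 1 adjusted over the list alone, camera adjusted p = 0.0683). The matrix protein fibronectin, FN1 (3.65 ± 0.15, adjusted p = 8.11e-07), and the transcription factor SNAI2 (3.40 ± 0.38, adjusted p = 2.25e-04) rose, and the intermediate filament gene VIM (-2.01 ± 0.38, adjusted p = 0.00467) fell.

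Target genes of BMP signalling rose in 7 of 14 cases, also adjusted over the list alone (camera adjusted p = 4.20e-05, and adjusted p = 0.207 with an estimated correlation). They included the BMP pseudoreceptor BAMBI (3.57 ± 0.31, adjusted p = 4.51e-05), the Notch effector HEY1 (3.37 ± 0.28, adjusted p = 3.50e-05) and BMP4 itself (1.94 ± 0.26). Hippo/YAP target genes rose in 8 of 10 cases and fell in 1, CCN2, in both adjustments (camera adjusted p = 1.04e-04, and adjusted p = 0.157 with an estimated correlation), with CRIM1 (1.95 ± 0.22) among the rises. Without APA-positive replicate 3 or SSEA5-positive replicate 1, CCN2 did not pass. Its other probe set, 17023646, did not pass on all arrays (-0.34, limma adjusted p = 0.202 over named probe sets). Nodal/Activin target genes fell in 6 of 10 cases and rose in none (7 fell adjusted over the list alone, camera adjusted p = 1.04e-04, and adjusted p = 0.277 with an estimated correlation), among them the ligands GDF3 (-3.46 ± 0.40, adjusted p = 2.74e-04), LEFTY2 (-3.20 ± 0.30, adjusted p = 7.61e-05) and NODAL (-2.06 ± 0.26, adjusted p = 4.58e-04). Wnt targets rose in 4 of 14 cases, with RNF43 (2.53 ± 0.22) the largest, and HOX genes in 5 of 22, with HOXB2 (4.79 ± 0.32) the largest. FGF/ERK targets fell in 6 of 13 cases and rose in 2, and ETV4 (-2.13 ± 0.19) had the largest fall. Adjusted over the list alone, 4 Wnt targets and 5 HOX genes rose, and 6 FGF/ERK targets fell and 3 rose. The HOX count was 3 without SSEA5-positive replicate 1. As lists, these 3 did not pass camera (adjusted p = 0.0886, 0.0954 and 0.151). They passed fry (adjusted p = 0.0151, 0.0196 and 0.0329), which does not compare a list with the other genes.

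DNA replication genes fell in 16 of 19 cases and rose in none (18 fell adjusted over the list alone, camera adjusted p = 5.16e-10, and adjusted p = 0.335 with an estimated correlation). The helicase subunit MCM6 (-1.38 ± 0.18, adjusted p = 4.86e-04), the origin factor CDC6 (-1.36 ± 0.22, adjusted p = 0.00213) and the replication factor GINS1 (-1.16 ± 0.12, adjusted p = 1.08e-04) were among them. The G2/M list fell by the same test (camera adjusted p = 1.67e-05, and adjusted p = 0.551 with an estimated correlation), with 8 of 22 members lower (11 adjusted over the list alone), BUB1 (-1.65 ± 0.33), a mitotic checkpoint kinase, the furthest. That member count moved to 2 without SSEA5-positive replicate 2, 3 without SSEA5-positive replicate 1 or 3, 4 without APA-positive replicate 3, 5 without APA-negative replicate 1 or 3 and 14 without APA-positive replicate 1. On the 3 APA-positive arrays the G2/M list averaged -0.19, -1.40 and -0.61 relative to the SSEA5-positive mean. Immediate-early genes, which respond to cell dissociation, rose in 4 of 14 cases (5 adjusted over the list alone, camera adjusted p = 0.0172, and adjusted p = 0.551 with an estimated correlation), among them FOS (2.20 ± 0.35, adjusted p = 0.00171) and JUN (1.93 ± 0.26, adjusted p = 7.15e-04). The immediate-early list lost its call without APA-positive replicate 1 (adjusted p = 0.0687).

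Other fixed lists did not pass camera in this comparison, although single members moved. The serine synthesis enzyme PSAT1 (-3.08 ± 0.27, adjusted p = 5.12e-05) and the interferon-induced IFITM1 (-1.71 ± 0.22, adjusted p = 5.47e-04) fell, and the 5-methylcytosine dioxygenase TET2 (2.15 ± 0.38, adjusted p = 0.00333) rose. Among markers of fibroblasts, the cell type of the feeder layer, LUM (4.50 ± 0.62, adjusted p = 7.63e-04) rose and THBS2 (-1.39 ± 0.16, adjusted p = 2.80e-04) fell, out of 8 measured. The vascular receptor KDR (-2.08 ± 0.22, adjusted p = 1.67e-04), which belongs to the mesoderm and endothelial lists, fell. Adjusted p values of these lists were primitive streak and mesoderm (0.439), definitive endoderm (0.343), neuroectoderm (0.241), primordial germ cell (0.991), naive pluripotency (0.661), endothelial and blood (0.152) and fibroblast (0.438) for cell types. For other processes they were CDK inhibitors and p53 targets (0.438), DNA methylation (0.53), MHC class I (0.438), glycolysis (0.0673), sterol synthesis (0.438), amino acid stress (0.383), interferon (0.0683) and ribosomal proteins (0.0842). Median, mean and test differed in sign for the fibroblast and DNA methylation lists, and the placental hormone, germ cell and naive medians lay below 0 with means above 0.

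The comparison of APA-negative with SSEA5-positive cells asked how BMP4-treated cells that carried little APA differed from undifferentiated cells. By camera the trophectoderm, amnion, keratin and junction lists shifted up, also with an estimated correlation. The pluripotency list shifted down, with a median of -0.84 against -2.13 in APA-positive cells, and did not pass with an estimated correlation (adjusted p = 0.112). WLS was 31.7-fold higher (4.99 ± 0.29, adjusted p = 1.70e-05), at 11.47 ± 0.19 against 6.49 ± 0.71 (SD, n = 3 each). HAPLN1, a hyaluronan link protein (probe set 16997802), rose by 4.94 ± 0.14 (adjusted p = 3.05e-07) from 3.95 ± 0.28 in SSEA5-positive cells (SD, n = 3), a value below the array medians. Of 14884 genes, 907 changed, 492 higher and 415 lower, and 351 of them differed by a log2 of at least 1 (221 higher, 130 lower). Groups did not overlap for 22.9% of genes, where chance gives 10%. Of 32 lists tested, 13 passed camera, and 4 with an estimated correlation. The count of 907 became 435 without APA-negative replicate 1 (260 higher, 175 lower), 455 without APA-negative replicate 2 (272 higher, 183 lower), 528 without SSEA5-positive replicate 1 (292 higher, 236 lower) and 504 without SSEA5-positive replicate 2 (285 higher, 219 lower).

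Trophectoderm regulators rose in 14 of 23 cases and fell in none (15 rose adjusted over the list alone, camera adjusted p = 1.54e-19, and adjusted p = 0.0287 with an estimated correlation). The rises included EPAS1 (4.72 ± 0.17, adjusted p = 1.76e-06), DLX5 (4.35 ± 0.27, adjusted p = 2.50e-05), TBX3 (3.89 ± 0.17, adjusted p = 3.97e-06) and GATA3 (3.62 ± 0.17, adjusted p = 6.00e-06). HAND1 (3.23 ± 0.24) and TFAP2C (1.89 ± 0.14) also rose, while GATA2 (0.35 ± 0.26, adjusted p = 0.56) and CDX2 (0.19 ± 0.09, adjusted p = 0.337) did not pass the test. Amnion genes rose in 6 of 9 cases, also adjusted over the list alone (camera adjusted p = 3.57e-09, and adjusted p = 0.0403 with an estimated correlation), among them ISL1 (4.63 ± 0.24, adjusted p = 7.25e-06) and VTCN1 (2.77 ± 0.33, adjusted p = 0.00117). Of 6 keratins, 4 rose (6 adjusted over the list alone, camera adjusted p = 5.13e-08, and adjusted p = 0.0426 with an estimated correlation), with KRT19 (2.00 ± 0.16, adjusted p = 1.05e-04) and KRT18 (1.67 ± 0.13, adjusted p = 9.78e-05) ahead of KRT7 (1.26 ± 0.22, adjusted p = 0.00812). Junction genes rose in 7 of 17 cases (9 adjusted over the list alone, camera adjusted p = 2.60e-06, and adjusted p = 0.0426 with an estimated correlation), among them the claudin CLDN10 (2.85 ± 0.37, adjusted p = 0.00208) and GRHL2 (1.92 ± 0.14, adjusted p = 6.91e-05). FN1 (3.32 ± 0.15, adjusted p = 3.97e-06) and SNAI2 (2.34 ± 0.38, adjusted p = 0.00664) rose among 10 mesenchymal transition genes, a list that passed (camera adjusted p = 0.0112, and adjusted p = 0.416 with an estimated correlation) but not without APA-negative replicate 1 (adjusted p = 0.0677).

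Pluripotency genes fell in 13 of 26 cases and rose in none (21 fell adjusted over the list alone, camera adjusted p = 1.09e-14, and adjusted p = 0.112 with an estimated correlation), with a median of -0.84. That member count moved to 6 without APA-negative replicate 1 or 2 or SSEA5-positive replicate 1 and 7 without SSEA5-positive replicate 2. The falls with calls that held whichever array was left out included USP44 (-2.96 ± 0.36, adjusted p = 0.00127) and POLR3G (-1.74 ± 0.21, adjusted p = 0.0012), a subunit of RNA polymerase III. POU5F1 (-0.82 ± 0.15, adjusted p = 0.0132) fell, but not without APA-negative replicate 1 (adjusted p = 0.0539), APA-negative replicate 2 (0.0545) or SSEA5-positive replicate 2 (0.0581). SOX2 (-1.61 ± 0.41, adjusted p = 0.0495) fell, but not without APA-negative replicate 1 (adjusted p = 0.153), APA-negative replicate 2 (0.177), APA-positive replicate 1 (0.056), APA-positive replicate 2 (0.0669), APA-positive replicate 3 (0.0678), SSEA5-positive replicate 1 (0.147), SSEA5-positive replicate 2 (0.135) or SSEA5-positive replicate 3 (0.112). DNMT3B (-0.99 ± 0.20, adjusted p = 0.0203) fell, but not without APA-negative replicate 1 (adjusted p = 0.0863), APA-negative replicate 2 (0.089), SSEA5-positive replicate 1 (0.0794) or SSEA5-positive replicate 2 (0.0785). NANOG (-1.03 ± 0.38, adjusted p = 0.179) did not pass the test.

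BMP target genes rose in 5 of 14 cases (6 adjusted over the list alone, camera adjusted p = 5.13e-08, and adjusted p = 0.104 with an estimated correlation), among them BAMBI (3.11 ± 0.31, adjusted p = 4.00e-04), the inhibitory SMAD gene SMAD6 (2.09 ± 0.30, adjusted p = 0.00339) and BMP4 (1.97 ± 0.26, adjusted p = 0.00211). Wnt targets rose in 3 of 14 cases, 4 adjusted over the list alone (camera adjusted p = 1.70e-04, and adjusted p = 0.112 with an estimated correlation). They were BMP4, RNF43 (1.69 ± 0.22, adjusted p = 0.00183) and LEF1 (1.46 ± 0.22, adjusted p = 0.00402). Hippo/YAP targets rose in 3 of 10 cases (6 adjusted over the list alone, camera adjusted p = 2.31e-04, and adjusted p = 0.139 with an estimated correlation), with AMOTL1 (0.93 ± 0.15) among them. The primitive streak and mesoderm list, genes of gastrulating cells, rose (camera adjusted p = 0.00186, and adjusted p = 0.416 with an estimated correlation), with 3 of 23 members higher (4 adjusted over the list alone). The Notch ligand DLL1 (1.47 ± 0.17, adjusted p = 0.00117) was the largest of them. That member count was 1 without APA-negative replicate 1 or 2 or SSEA5-positive replicate 1, 2 or 3 and 7 without APA-negative replicate 3. EOMES (1.75 ± 0.60, adjusted p = 0.145), a T-box factor of that list, did not pass the test and averaged 8.25 ± 1.31 in APA-negative and 6.50 ± 0.82 in SSEA5-positive cells (SD, n = 3 each). Its values on APA-negative replicates 1, 2 and 3 were 9.18, 8.83 and 6.76.

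The FGF/ERK list fell (camera adjusted p = 0.0348, and adjusted p = 0.469 with an estimated correlation), with 3 of 13 members lower and 1 higher (4 and 1 adjusted over the list alone) and ETV4 (-1.25 ± 0.19, adjusted p = 0.00484) the furthest down. The number higher was 0 without APA-negative replicate 1, 2 or 3 or APA-positive replicate 1, 2 or 3 or SSEA5-positive replicate 3. That list lost its call without APA-negative replicate 3 (adjusted p = 0.102), APA-positive replicate 3 (0.0554) or SSEA5-positive replicate 3 (0.149). DNA replication and G2/M genes moved down as lists with few single calls. For DNA replication, 1 of 19 members fell, GINS1 (6 adjusted over the list alone, median -0.39, camera adjusted p = 2.60e-06, and adjusted p = 0.416 with an estimated correlation). That count was 0 without APA-negative replicate 1 or SSEA5-positive replicate 1 or 2, 2 without APA-positive replicate 1 and 4 without APA-positive replicate 2. For G2/M, 0 of 22 fell by limma, also adjusted over the list alone, where 6 were lower at an unadjusted p under 0.05 (median -0.53, camera adjusted p = 1.89e-05, and adjusted p = 0.53 with an estimated correlation), and the count was 2 without APA-positive replicate 1 and 4 without APA-positive replicate 2. Single members of lists that did not pass included HOXB2 (3.33 ± 0.32, adjusted p = 3.62e-04) and LEFTY2 (-2.09 ± 0.30, adjusted p = 0.00335). Adjusted p values of those lists were placental hormones (0.706), extravillous trophoblast (0.408), definitive endoderm (0.408), neuroectoderm (0.723), primordial germ cell (0.158), naive pluripotency (0.129), endothelial and blood (0.706) and fibroblast (0.318) for cell types. For signalling and other processes they were Nodal/Activin targets (0.148), HOX genes (0.0583), CDK inhibitors and p53 targets (0.471), DNA methylation (0.851), MHC class I (0.984), glycolysis (0.103), sterol synthesis (0.723), amino acid stress (0.681), dissociation response (0.129), interferon (0.408) and ribosomal proteins (0.27). Median and mean differed in sign for definitive endoderm, neuroectoderm and DNA methylation, and the MHC class I test differed in sign from both.

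The comparison of APA-positive with APA-negative cells, sorted from the same kind of BMP4-treated culture, asked what set the APA-carrying cells apart. By camera the amnion, trophectoderm and keratin lists shifted up in APA-positive cells and the pluripotency, Nodal and primitive streak lists down, none of them with an estimated correlation. TRIM55, a muscle ubiquitin ligase (probe set 17069521), was 8.69-fold higher in APA-positive cells (3.12 ± 0.27, adjusted p = 4.86e-04). It averaged 9.61 ± 0.47 against 6.49 ± 0.36 (SD, n = 3 each). The largest rise was in LUM, a matrix gene and 1 of 8 fibroblast markers measured (3.26 ± 0.62, adjusted p = 0.0189), a call lost without APA-negative replicate 2 (adjusted p = 0.0676), APA-negative replicate 3 (0.0669), APA-positive replicate 2 (0.0631) or APA-positive replicate 3 (0.0665). The next rises after TRIM55 included IGFBP3 (2.90 ± 0.31, adjusted p = 0.00116), the matrix glycoprotein SPARCL1 (2.87 ± 0.17, adjusted p = 1.08e-04) and VTCN1 (2.64 ± 0.33, adjusted p = 0.00226). SFRP2 (probe set 16980762) was 7.71-fold lower (-2.95 ± 0.44, adjusted p = 0.0053), and GDF3 (-2.92 ± 0.40, adjusted p = 0.00387) and the neuropeptide gene NMU (-2.25 ± 0.27, adjusted p = 0.00198) were lower too. Of 14884 genes, 565 changed, 377 higher and 188 lower, and 258 of them differed by a log2 of at least 1 (190 higher, 68 lower). This fit did not use the pairing of these arrays by replicate number. With the number as a block, 729 genes changed. Groups did not overlap for 18.7% of genes, where chance gives 10%. Of 32 lists tested, 11 passed camera, and 0 with an estimated correlation. The count of 565 became 357 without APA-negative replicate 2 (248 higher, 109 lower) and 339 without APA-negative replicate 3 (226 higher, 113 lower). The lower count of 188 also became 118 without APA-negative replicate 1, 113 without APA-positive replicate 2 and 103 in the fit of only the 2 groups compared.

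Pluripotency genes fell in 13 of 26 cases and rose in none (20 fell and 1 rose adjusted over the list alone, camera adjusted p = 1.69e-16, and adjusted p = 0.136 with an estimated correlation), with a median of -1.14. The number of rises was 1 without APA-negative replicate 3. SOX2 (-2.24 ± 0.41, adjusted p = 0.0155) fell, but not without APA-positive replicate 1 (adjusted p = 0.0531). PRDM14 (-2.30 ± 0.43, adjusted p = 0.0174) fell, but not without APA-negative replicate 2 (adjusted p = 0.0508), APA-positive replicate 1 (0.0584) or APA-positive replicate 3 (0.060). NANOG (-1.57 ± 0.38, adjusted p = 0.0553) did not pass the test and passed with the replicate number as a block (adjusted p = 0.00803). POU5F1 (-0.42 ± 0.15, adjusted p = 0.208) and DNMT3B (-0.37 ± 0.20, adjusted p = 0.446) did not pass. Nodal/Activin targets fell in 3 of 10 cases, GDF3, NODAL and EOMES (8 adjusted over the list alone, median -1.09, camera adjusted p = 8.86e-07, and adjusted p = 0.182 with an estimated correlation), and that count was 1 without APA-negative replicate 1 or 2 or APA-positive replicate 2 or 3. The other NODAL probe set, 16705721, did not pass on all arrays (-1.09, limma adjusted p = 0.0779 over named probe sets). The primitive streak and mesoderm list fell (camera adjusted p = 2.53e-06, and adjusted p = 0.219 with an estimated correlation), with 2 of 23 members lower, EOMES and KDR (3 adjusted over the list alone). That count was 1 without APA-negative replicate 1 or 2 or APA-positive replicate 1 or 3 or SSEA5-positive replicate 1 and 5 without APA-negative replicate 3. KDR (-2.08 ± 0.22, adjusted p = 0.00116) held in every fit that left out an array. EOMES (-2.82 ± 0.60, adjusted p = 0.0318) fell, but not without APA-negative replicate 1 (adjusted p = 0.101), APA-negative replicate 2 (0.114), APA-positive replicate 1 (0.066), APA-positive replicate 2 (0.106), APA-positive replicate 3 (0.0763) or SSEA5-positive replicate 1 (0.0567). The definitive endoderm list also fell (median -0.33, camera adjusted p = 0.00516, and adjusted p = 0.339 with an estimated correlation), with 0 of 14 members passing limma in either adjustment and 5 lower at an unadjusted p under 0.05.

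Trophectoderm regulators rose in 6 of 23 cases and fell in 1, EOMES (15 rose and 2 fell adjusted over the list alone, camera adjusted p = 4.56e-08, and adjusted p = 0.115 with an estimated correlation). The number of falls was 0 without APA-negative replicate 1 or 2 or APA-positive replicate 1, 2 or 3 or SSEA5-positive replicate 1. The rises included GCM1 (2.02 ± 0.27, adjusted p = 0.00341), a placental transcription factor, the TEAD cofactor VGLL1 (2.02 ± 0.21, adjusted p = 0.00116), EPAS1 (1.85 ± 0.17, adjusted p = 6.02e-04) and HAND1 (1.34 ± 0.24, adjusted p = 0.0129). Other regulators did not pass: GATA3 (0.58 ± 0.17, adjusted p = 0.123), GATA2 (0.78 ± 0.26, adjusted p = 0.164), TFAP2C (-0.25 ± 0.14, adjusted p = 0.461) and CDX2 (0.25 ± 0.09, adjusted p = 0.221). Amnion genes rose in 4 of 9 cases (5 adjusted over the list alone, camera adjusted p = 4.70e-08, and adjusted p = 0.115 with an estimated correlation), IGFBP3, VTCN1, HEY1 (2.13 ± 0.28, adjusted p = 0.00288) and TBX3 (1.36 ± 0.17, adjusted p = 0.00226). Of 6 keratins, 4 rose (5 adjusted over the list alone, camera adjusted p = 3.60e-06, and adjusted p = 0.115 with an estimated correlation), with KRT19 (1.05 ± 0.16, adjusted p = 0.0053) among them. That count was 1 without APA-negative replicate 3 and 2 without APA-negative replicate 2 or APA-positive replicate 1, 2 or 3. KRT7 (1.08 ± 0.22, adjusted p = 0.0237) rose, but not without APA-negative replicate 3 (adjusted p = 0.0537), APA-positive replicate 1 (0.072), APA-positive replicate 2 (0.0705) or APA-positive replicate 3 (0.0565). Junction genes rose in 2 of 17 cases, GRHL1 and JUP (5 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.00663, and adjusted p = 0.182 with an estimated correlation), and in 1 without APA-positive replicate 2 or 3, and the number of falls, 0 with all arrays, was 1 without APA-positive replicate 1. The call of JUP (0.98 ± 0.15, adjusted p = 0.00732) held in every such fit, and that of GRHL1 (1.63 ± 0.35, adjusted p = 0.0333) was lost without APA-positive replicate 1 (adjusted p = 0.0588), APA-positive replicate 2 (0.106), APA-positive replicate 3 (0.0612), SSEA5-positive replicate 1 (0.0614), SSEA5-positive replicate 2 (0.0567) or SSEA5-positive replicate 3 (0.0509). Hippo/YAP targets rose in 2 of 10 cases, TEAD1 and ARHGEF17, and fell in 1, CCN2 (4 and 1 adjusted over the list alone, camera adjusted p = 0.00233, and adjusted p = 0.227 with an estimated correlation). The Hippo/YAP count of rises was 0 without APA-negative replicate 2 or 3 or APA-positive replicate 2 and 1 without APA-negative replicate 1 or APA-positive replicate 3, and CCN2 did not pass without APA-negative replicate 1, 2 or 3 or APA-positive replicate 2 or 3. The other CCN2 probe set, 17023646, did not pass on all arrays (-0.44, limma adjusted p = 0.224 over named probe sets).

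DNA replication genes fell in 2 of 19 cases, MCM6 and GINS1 (12 adjusted over the list alone, median -0.44, camera adjusted p = 7.78e-09, and adjusted p = 0.339 with an estimated correlation), and that count was 0 without APA-negative replicate 1 or 3 or APA-positive replicate 2 or 3, 1 without APA-negative replicate 2 and 4 without APA-positive replicate 1. The immediate-early list rose (camera adjusted p = 0.0448, and adjusted p = 0.564 with an estimated correlation), with JUN the 1 member of 14 to rise in either adjustment. It lost its call without APA-negative replicate 3 (adjusted p = 0.195) or APA-positive replicate 1 (0.252) and with the replicate number as a block (adjusted p = 0.0697). JUN itself did not pass without APA-negative replicate 1 or 3 or APA-positive replicate 1 or 3 or SSEA5-positive replicate 2. Single changes in lists that did not pass included falls of PSAT1 (-2.03 ± 0.27, adjusted p = 0.00322) and IFITM1 (-1.81 ± 0.22, adjusted p = 0.00218) and a rise of PAPPA2 (1.80 ± 0.28, adjusted p = 0.00665). The G2/M list (adjusted p = 0.0544) and the interferon list (adjusted p = 0.085) did not pass, and passed with the block (adjusted p = 0.0235 and 0.0311). Adjusted p values of the other lists were placental hormones (0.709), extravillous trophoblast (0.508), mesenchymal transition (0.507), neuroectoderm (0.223), primordial germ cell (0.084), naive pluripotency (0.508), endothelial and blood (0.144) and fibroblast (0.893) for cell types. For signalling and other processes they were BMP targets (0.508), Wnt targets (0.43), FGF/ERK targets (0.508), HOX genes (0.473), CDK inhibitors and p53 targets (0.629), DNA methylation (0.347), MHC class I (0.223), glycolysis (0.223), sterol synthesis (0.507), amino acid stress (0.223) and ribosomal proteins (0.186). The placental hormone, BMP target, HOX, naive and fibroblast lists, none of which passed, had a median, mean or test that differed in sign.

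**Figure D2:**
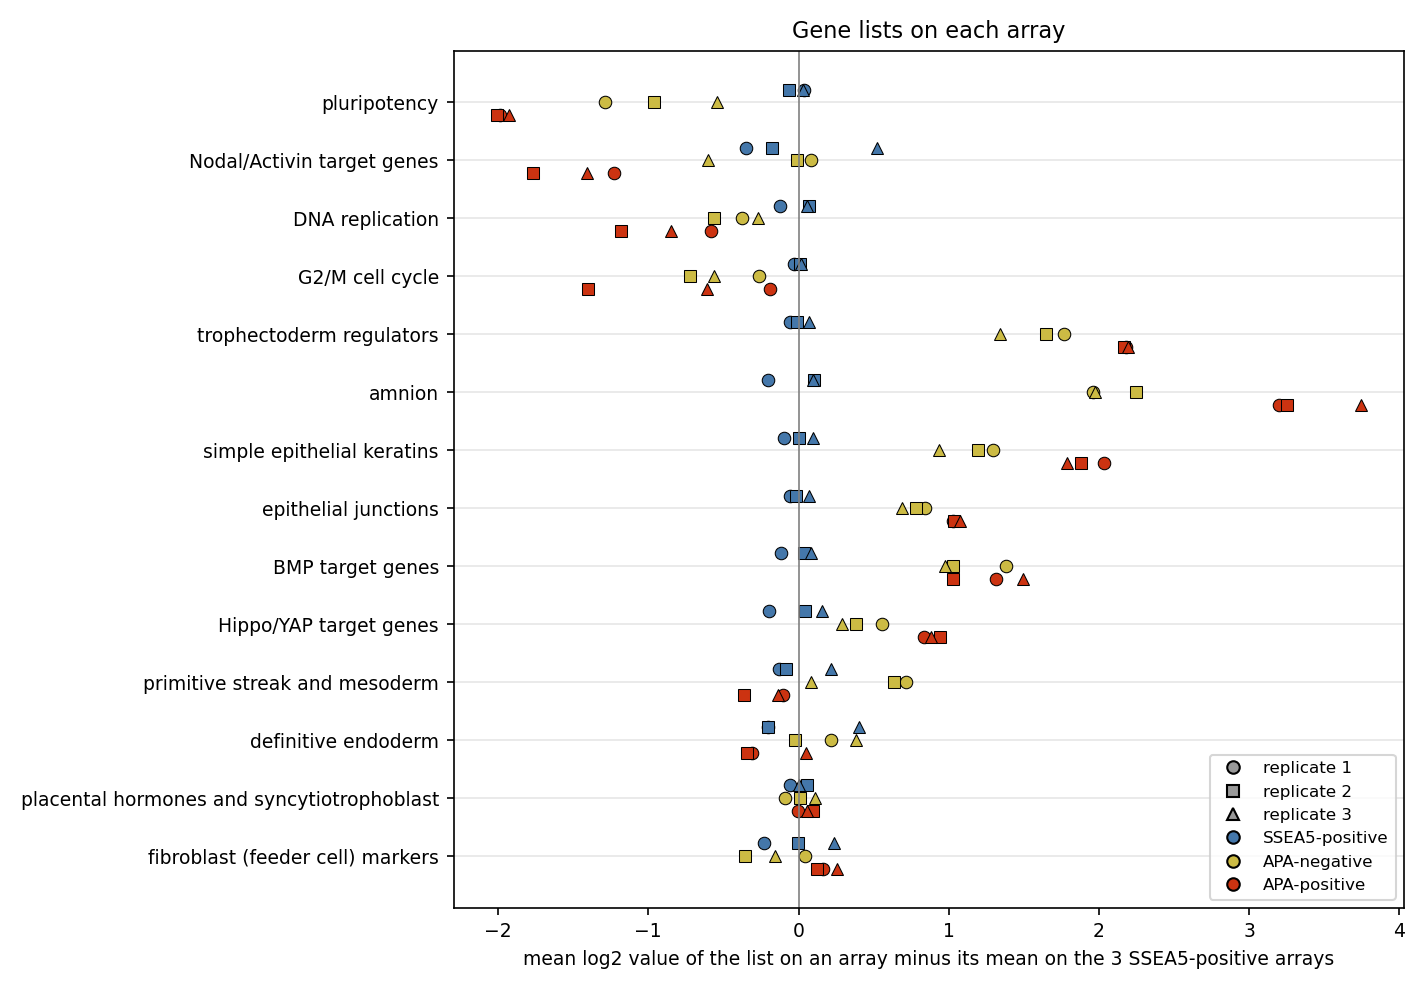
Mean log2 value of 14 fixed gene lists on each array minus the mean of the 3 SSEA5-positive arrays (x axis, log2), with lists along the y axis and 1 point per array coloured by sorted population. Pluripotency genes lay at -1.29, -0.96 and -0.54 on the 3 APA-negative arrays.

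Across the 3 populations, 2361 of 14884 genes differed by limma's moderated F test. Both BMP4-treated populations changed many of the same genes relative to SSEA5-positive cells. Of the genes called in each comparison, 456 rose in both and 394 fell in both, where independent lists would share 51.0 and 40.5. Among the shared rises were EPAS1, ISL1, TBX3, GATA3 and WLS, and among the shared falls USP44, LEFTY2 and POLR3G. Another 2142 genes were called in APA-positive cells alone and 54 in APA-negative cells alone, which by itself does not show that they differed between the populations. Across genes, which are not independent replicates, both sets of differences correlated at r = 0.847 (rho = 0.758), against 0.50 in the simulation. Their covariance was 0.202 against 0.0163 simulated, and 77.2% of genes had the same sign against 66.7%. The simulated unchanged groups also shared their SSEA5-positive arrays, but each array was drawn independently. Deviations of same-numbered APA-negative and APA-positive arrays correlated at 0.224 to 0.349 in the data. The simulated covariance leaves that shared spread out. Anything common to the 3 SSEA5-positive arrays, such as growth on feeder cells with basic fibroblast growth factor, enters both sets of differences. These arrays were too few to divide, so that part cannot be told apart. The shared count of 850 became 421 without APA-negative replicate 1, 439 without APA-negative replicate 2, 508 without SSEA5-positive replicate 1 and 490 without SSEA5-positive replicate 2.

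**Figure D3:**
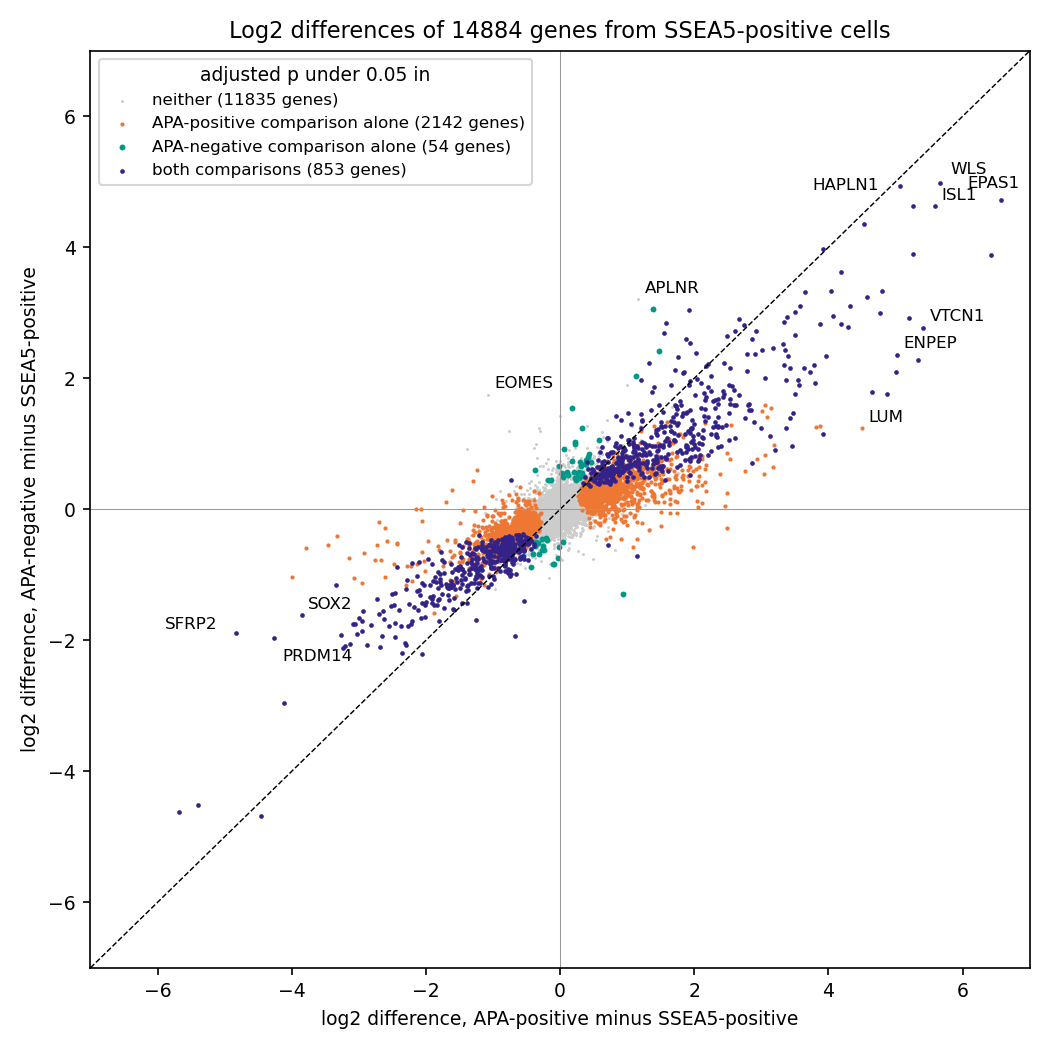
Log2 differences of 14884 genes from SSEA5-positive cells in APA-positive (x axis) and APA-negative cells (y axis), 1 point per gene, coloured by the comparisons in which the gene passed, with a dashed line of equal differences. EPAS1 lay at 6.57 and 4.72, and SOX2 at -3.85 and -1.61.

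For 196 genes all 3 comparisons passed and APA-negative cells lay between the other populations, with 131 rising from SSEA5-positive through APA-negative to APA-positive cells and 65 falling. The graded rises with the largest steps included VTCN1, which averaged 5.21 ± 0.51, 7.98 ± 0.54 and 10.63 ± 0.41 in that order (SD, n = 3 each). TCIM, a regulator of Wnt signalling, rose by 2.92 ± 0.21 and a further 2.28 ± 0.21, IGFBP3 by 2.09 ± 0.31 and 2.90 ± 0.31, and the adaptor gene DOK4 by 1.93 ± 0.23 and 1.87 ± 0.23. KLHL4 fell in steps of -1.56 ± 0.21 and -1.38 ± 0.21. APA-negative cells lay above both other populations for 8 genes and below both for 8. Among those below, the Wnt modulator SFRP1 (probe set 17076609) differed from SSEA5-positive cells by -1.93 ± 0.19, and APA-positive from APA-negative cells by 1.25 ± 0.19. ACSL1, which activates long-chain fatty acids (probe set 16982047), moved by -0.71 ± 0.11 and 1.86 ± 0.11. Among those above, the chemokine gene CXCL12 (1.03 ± 0.17, adjusted p = 0.00623) rose, and APA-positive cells differed from APA-negative ones by -0.81 ± 0.17 (adjusted p = 0.0278), a call lost without APA-negative replicate 2 (adjusted p = 0.0937), APA-negative replicate 3 (0.104), APA-positive replicate 1 (0.0829) or APA-positive replicate 2 (0.092). The outside-range count of 16 became 6 without APA-negative replicate 1 or 2, 7 without SSEA5-positive replicate 2 or 3, 8 without SSEA5-positive replicate 1 and 10 without APA-positive replicate 3, and 31 with the replicate number as a block. The count of 196 became 92 without APA-negative replicate 2, 100 without APA-negative replicate 1, 115 without APA-negative replicate 3 or SSEA5-positive replicate 2 and 117 without SSEA5-positive replicate 1.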

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

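Tests of mixed cells, of exchanged labels, of a mixed APA-negative population (range and share) and of feeder culture were chosen only after the results were seen. The test without APA-positive replicate 2 and the splits of the arrays were planned.

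As lists, primitive streak and mesoderm genes, with a mean log2 difference of -0.68, and definitive endoderm genes, with -0.39, were lower in APA-positive than in APA-negative cells by camera (adjusted p = 2.53e-06 and 0.00516) and not with an estimated correlation (adjusted p = 0.219 and 0.339). By limma, 2 of 23 and 0 of 14 members fell, and 12 and 5 were lower at an unadjusted p under 0.05. The streak count was 1 without APA-negative replicate 1 or 2 or APA-positive replicate 1 or 3 or SSEA5-positive replicate 1 and 5 without APA-negative replicate 3. Within APA-negative cells, replicate 3 stood apart: MIXL1 and APLNR, named after their values were seen, reached 9.72 and 10.28 in the mean of replicates 1 and 2 and 6.42 and 7.17 in replicate 3. Undifferentiated cells mixed into replicate 3 would need 1 share for all genes. The share needed was 0.934 for APLNR, 0.984 for EOMES, 1.28 for MIXL1 and 0.329 for DLL1, and lay between -0.672 and 0.871 for 12 trophectoderm regulators (difference of medians 0.601), so the ranges overlap. Relative to SSEA5-positive arrays, the pluripotency list of APA-negative replicate 3 lay at -0.54, against -1.29 and -0.96 in replicates 1 and 2, and its trophectoderm list at 1.34 against 1.76 and 1.65, as a share of undifferentiated cells would give. APLNR, EOMES and MIXL1 lay above all 12, and DLL1 did not. The streak genes were examined because replicate 3 was low in them, and each share rests on that 1 array without an error. The shares thus do not decide, and a mixture stays open as a part or the whole of the cause. An exchange of labels with SSEA5-positive replicate 3 is excluded. Its trophectoderm regulators lay 0.103 from the other SSEA5-positive arrays, where APA-negative replicates 1 and 2 lay 1.74 above. A difference between differentiation experiments stays open and untested. Deviations of APA-negative replicate 3 correlated at 0.335 with those of APA-positive replicate 3 and at 0.173 with those of SSEA5-positive replicate 3.

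In 16 genes APA-negative cells lay outside the range of the other populations, and 3 genes were called in opposite directions against SSEA5-positive cells. These 3, ACSL1, C3orf52 and EFNA5, of which EFNA5 was named after its values were seen, differed by 1.14 ± 0.11, 0.72 ± 0.13 and -0.73 ± 0.11 in APA-positive and by -0.71 ± 0.11, -0.55 ± 0.13 and 0.45 ± 0.11 in APA-negative cells (adjusted p of the difference between treated populations 1.08e-04, 0.00108 and 5.91e-04). C3orf52 lost its APA-negative call without APA-negative replicate 1 (adjusted p = 0.124), APA-negative replicate 2 (0.0716), APA-negative replicate 3 (0.107), APA-positive replicate 3 (0.0588), SSEA5-positive replicate 1 (0.0617), SSEA5-positive replicate 2 (0.147) or SSEA5-positive replicate 3 (0.0977). APA-negative cells could be a mixture of undifferentiated-like and APA-positive-like cells, which would keep every gene inside the range: simulations held inside it gave up to 20 such genes (median 11), and at a threshold of 0.01 up to 4 (median 1), where ACSL1 and SFRP1 passed both tests. With the replicate number as a block, 31 genes lay outside, where simulations with the block gave up to 24 (median 14). The block also joins SSEA5-positive arrays, of which replicate 1 did not pair by number, so this count does not decide. A mixture also needs 1 share of APA-positive cells for all genes of an array. Of 996 genes called with a log2 difference of at least 1 between APA-positive and SSEA5-positive cells, 245 (24.6%) deviated from a mixture with a share fitted to each array (adjusted p under 0.05), and 79 (7.93% of all 996) did so by a log2 of at least 1, less than the 10% set for excluding it. The shares fitted were 0.553, 0.523 and 0.367 on APA-negative replicates 1, 2 and 3. The median share needed was 0.355 for genes higher in APA-positive than in SSEA5-positive cells and 0.701 for genes lower. The quartiles of these shares were 0.211 to 0.563 and 0.551 to 0.819. Of the 79 genes, 65 lay below the mixture and 14 above it. The fit took array values as linear in RNA amount, which was not tested. A mixture was also set to leave under 10% of genes deviating at that adjusted p, and 24.6% did. If array values are linear, this and the unlike shares argue against 1 share per array for these genes. By the 10% bound on deviations of at least 1, a mixture of cells like those of the other populations was not excluded. A population with a state of its own stays open too.

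DNA replication genes were lower in APA-positive than in SSEA5-positive cells, with 16 of 19 members called and a median of -0.92 (camera adjusted p = 5.16e-10, and adjusted p = 0.335 with an estimated correlation). APA-positive replicate 2 alone was not the cause: without it the median was -0.748, camera gave adjusted p = 2.23e-09 and 12 members fell. Growth on feeder cells or on Matrigel does not differ between the treated populations, so it could not cause a difference between them. The list was lower in APA-positive than in APA-negative cells by camera (adjusted p = 7.78e-09). It did not pass with an estimated correlation (adjusted p = 0.339) or by fry (adjusted p = 0.0831). Whether the treated populations differ in this list is thus not settled, and no conclusion on growth is drawn from it. For the part between APA-negative and SSEA5-positive cells, a median of -0.393, several factors change together. Feeder culture, basic fibroblast growth factor and BMP4 treatment thus cannot be told apart. A lower rate of division in APA-positive cells may account for a difference between the treated populations and was not measured here.

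Probe sets with no gene name also changed, in data that the comparisons of genes leave out. Of 37519, 2189 differed between APA-positive and SSEA5-positive cells (1093 higher, 1096 lower), 473 between APA-negative and SSEA5-positive cells (254 higher, 219 lower) and 258 between APA-positive and APA-negative cells (155 higher, 103 lower).

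Other splits of the arrays were compared with the real one. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. In each comparison 1 of 10 splits, the real one, gave as many genes: 2995, 907 and 565, where the highest other split gave 0. For lists, the real splits gave 11, 13 and 11 and the highest others 10, 12 and 7, again 1 of 10 each. Against SSEA5-positive cells, other splits thus called nearly as many lists by camera. The number of lists called there hardly sets the real grouping apart. Of the 9 other splits of APA-positive and APA-negative arrays, the 3 that part all same-numbered pairs gave 0 genes, as did the 6 that do not. Over all 9 arrays, 100 of 280 splits were drawn, and 1, the real one, gave as many genes by F test (2361, highest other 1000). It alone also gave as many in the overlap (850, highest other 629) and in the graded pattern (196, highest other 0). Chance is thus excluded for a difference among the 3 populations. It is not excluded for the overlap or the graded pattern by themselves, since these splits mix all populations at once.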

How the results depend on the processing

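The fits without APA-negative replicate 3 and SSEA5-positive replicate 3, without all arrays numbered 3, and with the block in the APA-positive and APA-negative arrays alone were chosen after the results were seen, and the rest were planned. No called direction reversed under any alternative run. Of 4927 planned values for 274 named gene comparisons, 4262 kept their side of the threshold, 660 lost it and 5 gained it, and in 618 added ones these were 447, 167 and 4. Of 1725 planned list values, 1635 kept their side, 47 lost it and 43 gained it, and in 224 added ones 212, 4 and 8. Uncalled lists changed sign in 31 and 17 of these. For APA-positive against SSEA5-positive, APA-negative against SSEA5-positive and APA-positive against APA-negative cells, in that order, 2995, 907 and 565 genes became 779, 191 and 95 with treat at a log2 of 0.5 and 1754, 382 and 252 at a threshold of 0.01, as stricter tests call fewer. With treat, 67.5% of APA-negative calls against SSEA5-positive cells were higher, against 54.2%. Testing every probe set gave 4534 for the first, counted in probe sets. Without all arrays numbered 3, fewer arrays gave 591 and 139 for the APA-negative against SSEA5-positive and the APA-positive against APA-negative comparison, 1351 by F test (2361 with all), 554 for the overlap (850) and 48 graded genes (196). Without APA-negative replicate 3 and SSEA5-positive replicate 3 APA-positive against APA-negative cells gave 271 genes and 99 graded genes. The lower counts were 902 in the first comparison without all arrays numbered 3 (1452 with all) and 274 in the second without APA-negative replicate 3 and SSEA5-positive replicate 3 (415). Leaving out 1 array gave 2273 to 2838, 435 to 950 and 339 to 509 genes, 1628 to 2211 by F test, 421 to 861 for the overlap, 92 to 179 graded and 6 to 18 outside-range genes (16 with all). Lists called were 11, 13 and 11, and 11 to 14, 12 to 15 and 11 to 13 with 1 array left out. With an estimated correlation they were 2, 4 and 0, and with fry 20, 12 and 9. Of the lists called by camera, fry did not call G2/M in the first comparison. In the second it did not call primitive streak and mesoderm, FGF/ERK targets, G2/M or DNA replication. In the third it did not call definitive endoderm, DNA replication or immediate-early genes. The cause was not tested for the change with fry, whose question differs.

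With the replicate number as a block, the counts were 3406, 1094 and 729 genes, 2702 by F test, 1013 for the overlap, 246 graded and 31 outside-range genes, and 12, 13 and 12 lists. The block within APA-positive and APA-negative arrays alone gave 629 genes and 12 lists. Of 264 called named gene comparisons, 257 kept their call under the block and 7 lost it, and 2 of 10 uncalled ones gained one. In APA-positive against APA-negative cells, where the numbers pair the arrays, the block ended the calls of CALD1 (adjusted p = 0.0655) and HOXB2 (adjusted p = 0.0526) and changed no other call than those given with the comparison. SSEA5-positive arrays share only a number with the others, and not every one correlated best with its own number: same-numbered arrays correlated at -0.0980, 0.0784 and 0.173 with APA-negative and at -0.0498, 0.132 and 0.272 with APA-positive cells. A median standard error of 0.135 and 3 arrays per population limit small differences, and signal over background, which the files do not give, limits dim genes.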

Other observations

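The gene groups below were all formed after the data were seen and are reported as values. Probe sets of the miR-302 cluster, microRNAs of pluripotent cells, fell in APA-positive cells. All 5 (MIR302A, MIR302B, MIR302C, MIR302D and MIR367) were lower than in SSEA5-positive cells, by log2 differences of -3.99 to -2.76 with a median of -3.33, and lower than in APA-negative cells, by -3.20 to -1.99 with a median of -2.92. MIR302A, for example, differed by -3.79 ± 0.38 and -3.20 ± 0.38 (adjusted p = 1.07e-04 and 0.00195). Between APA-negative and SSEA5-positive cells 0 of the 5 passed limma and 3 were lower at an unadjusted p under 0.05, with differences of -1.03 to -0.41 and a median of -0.74. The probe sets report transcripts of the locus and not mature microRNAs, and the 5 lie in 1 transcript, so they are not independent.

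Genes that share a symbol stem were compared as 229 families of at least 8 genes with camera. In APA-positive against SSEA5-positive cells, 11 of 36 VPS genes, which sort vesicle cargo, rose and none fell (adjusted p = 0.00296), and 5 of 10 HOXB genes rose (adjusted p = 0.0112). Falls were seen in 7 of 11 MCM genes (adjusted p = 0.00827), in 7 of 24 NUP genes of the nuclear pore (adjusted p = 0.0112) and in 14 of 40 kinesins, while 3 rose (adjusted p = 0.0276). All 8 SNAR genes fell (median -2.31, adjusted p = 2.87e-08), which are near-identical copies and count as uncertain. In APA-negative against SSEA5-positive cells, 3 of 18 annexins and 3 of 8 SOCS genes rose (adjusted p = 0.0239 and 0.0499), 7 of 8 SNAR genes fell (adjusted p = 7.42e-11), and 5 of 40 kinesins fell and 2 rose (adjusted p = 0.0239). In APA-positive against APA-negative cells camera called shifts with few members passing limma. VPS genes shifted up with 2 of 36 passing (adjusted p = 0.0148) and ATF genes with 0 of 8 and 3 higher at an unadjusted p under 0.05 (adjusted p = 0.0488). SNAR, MCM and EXOSC genes shifted down, with 3 of 8, 1 of 11 and 0 of 10 passing, the last with 3 lower at an unadjusted p under 0.05 (adjusted p = 2.84e-04, 0.042 and 0.0488). None of these families passed with an estimated correlation (adjusted p = 0.993, 0.999 and 0.994 in these comparisons).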
